A study of Sus scrofa with 4 samples.

How the data were processed

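Poly(A)-enriched RNA of 4 pig (Sus scrofa) ovary samples, all taken in diestrus, was sequenced on an Illumina NovaSeq instrument, per the labels' protocols. The samples formed 2 groups of 2: wild type (WT) and leptin overexpression. The leptin overexpression animals were described in the series design as second-generation offspring of crosses that began with a cloned transgenic boar. The libraries were made with the NEBNext Ultra RNA kit; whether the counting used strand was not given in the sources used here, so reads of overlapping or antisense genes cannot be assigned with certainty.

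The deposited expected counts per gene were estimated counts that need not be whole and were not scaled to depth, per the file headers. The deposited FPKM values, made by the authors, were scaled to transcript length and to the number of fragments, per the file headers. The submitters' processing notes name fastp 0.18.0, Bowtie2 2.2.8, HISAT2, StringTie 1.3.1, RSEM, DESeq2 and edgeR 3.32.0, with no roles or order; the genome build was not given in the sources used here, and no coordinates are reported. The table held 22309 genes, 21295 with Ensembl identifiers and 1014 with identifiers of assembled genes. Symbols came from the table for 15153 genes, from a reference table of gene names for 664, and from a RefSeq table (Sscrofa11.1) for 2222 through the NCBI gene identifier in the description; 4270 genes had no symbol. The last of these matches was added after gene list tests without it had been seen. Columns named for controls were matched to the WT samples of the same number.

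Expected counts were rounded to whole numbers. Totals were 16493113 to 16797511 per library, so 3 counts, the limit that a count of 0 allows, came to 0.179 to 0.182 CPM (the count of a gene scaled to a fixed library total) before scaling and to 0.136 to 0.224 after TMM scaling. Binomial and counting intervals and the floors cover counting error only. Bootstrap intervals, from 2000 draws over the genes of a list, treat these genes as independent and hold no spread between samples. Genes were kept with edgeR's filterByExpr, which left 13937 and removed 8372. Libraries were scaled with TMM factors, and the groups were compared with edgeR's quasi-likelihood test (edgeR 4.0.16, limma 3.58.1, R 4.3.3; robust dispersion, genotype as the only covariate, 2 residual degrees of freedom). P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. All adjusted p-values of single genes are from edgeR's quasi-likelihood test unless another tool is named. Log2 fold changes are leptin overexpression minus WT, given with standard errors (SE). The SE of edgeR values is an approximation, the absolute log2 fold change divided by the square root of the test's F statistic. CPM values are TMM-normalised. The labels do not say that the 2 samples of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical.

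Before the data were examined, 47 gene lists, the tests, the alternatives and a rule for named genes were fixed. Of 983 list entries, 905 matched a row and 843 were tested. Lists with at least 5 tested genes, 46 in all, were compared with all other tested genes by camera on log2 CPM (prior count 2, preset correlation 0.01), adjusted over the lists; the erythroid list had 3 tested genes and was not tested. The difference of a list is the mean log2 change of its genes minus that of all other tested genes. Members were also adjusted over the list alone. KEGG pathways and gene ontology (GO) terms of 10 to 500 genes in the deposited table were tested with one-sided Fisher's exact tests against the tested genes that carried a term.

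The rule named LEP and LEPR; up to 8 genes per direction with the largest changes and 4 with the highest mean CPM, among those past the threshold with a symbol, a mean of at least 5 CPM and groups that did not overlap; up to 4 members per list past the threshold, or the 2 with the highest mean CPM where none passed and the list is described; and STAR, CYP11A1, HSD3B1, CYP17A1, CYP19A1, BAX and BCL2. Some other genes that these rules select are not reported here. LOC100520618, which has no other symbol, list members past the threshold over the list alone, genes called by DESeq2, and ODC1, ZP3, BMP15 and GDF9 were named after their values were seen, and the lists described gene by gene were also chosen then. BCL2 matched no row by symbol and was not analysed here. BAX was taken from the row that the table described as BCL2 associated X while giving it another symbol, DHDH.

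The alternatives were RLE and upper-quartile factors, no filter, a filter of 1 CPM in 2 samples, DESeq2 1.42.0, limma-voom, limma-trend on log2(FPKM + 1), a fold threshold of 2, the replicate number as a block, and each library left out. Leaving out 1 library leaves a group with a single sample, which is then assumed to vary like the other group. Gene lists were also tested with an estimated correlation and with fry. Camera on the KEGG and GO terms and the adjustment over the list alone were added after seeing the data.

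On simulated counts for the 13937 genes, with 200 genes changed, edgeR recovered 39% of 4-fold and 94% of 16-fold changes and called 3 unchanged genes among 136 calls. DESeq2 recovered 51% and 92%, with 20 unchanged genes among 164 calls. Every gene was drawn with the dispersion trend and with the same mean level in all libraries of a group. No gene varied beyond the trend and no library was an outlier, so these rates need not hold for the real libraries. Camera recovered a simulated 2-fold shift of a list of 19 genes and called 0 of 45 other lists, in counts simulated without correlation between genes.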

Results

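Messenger RNA of pig ovaries in diestrus was measured in 2 WT samples and 2 samples from sows that overexpress leptin, the adipocyte hormone that reports fat stores. Total counts were 16493113 and 16797511 in WT replicates 1 and 2 and 16563376 and 16564990 in leptin overexpression replicates 1 and 2. Levels are given in that order, WT against leptin overexpression. WT replicate 2 correlated more closely with leptin overexpression replicate 1 (Pearson's r = 0.941 across genes, which are not independent replicates) than with WT replicate 1 (0.917), and the leptin overexpression libraries correlated at 0.936; the other pairs across the groups correlated less, at 0.856 to 0.892. TMM factors were 1.34 and 0.998 in WT and 0.925 and 0.809 in leptin overexpression. Mitochondrially encoded genes took 6.89% and 12.9% of counts in WT and 15.1% and 16.4% in leptin overexpression; the exact binomial 95% interval of the first was 6.88% to 6.91%.

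The comparison of the genotypes asks which ovarian transcripts differ in sows with leptin overexpression. LEP (ENSSSCG00000040464), the overexpressed gene, had 0 and 3 counts in the WT libraries and 55 and 124 in the leptin overexpression libraries, or 3.59 and 9.26 CPM. The ratio of pooled counts per TMM-scaled library size was 80.7 (95% counting interval 27.2 to 395). Its log2 fold change of 6.18 (SE 1.19) did not pass the threshold over all genes (edgeR adjusted p = 0.198), and passed when adjusted over the list alone in the leptin and JAK-STAT list (0.0141) and the adipocyte list (0.00734). The log2 fold change of LEP was 5.07 without WT replicate 1 and 9.74 without WT replicate 2, the latter resting on 0 counts in WT. Without leptin overexpression replicate 1 or 2 it was 6.72 or 5.33. LEPR (ENSSSCG00000025188), the leptin receptor, was at 2.63 and 26.5 CPM in WT and 15.5 and 21.5 in leptin overexpression (log2 fold change 0.35, SE 0.94, edgeR adjusted p = 0.91). Without WT replicate 1 the log2 fold change of LEPR was -0.54, and without WT replicate 2 it was 2.78. These fits hold none of the spread within WT.

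Of 13937 genes tested, 4 rose in leptin overexpression and 0 fell. STMN2 (ENSSSCG00000006160), a microtubule-binding protein best known from neurons, went from 0.263 ± 0.0506 CPM (SD, n = 2) to 36.3 ± 1.42. NEFL (ENSSSCG00000009649), the neurofilament light chain, went from 0.565 ± 0.292 to 45.1 ± 7.84 CPM, and LGI2 (ENSSSCG00000028927), a leucine-rich repeat protein, from 1.81 ± 0.896 to 55.3 ± 17.5. LOC100520618 (ENSSSCG00000003599), described as ornithine decarboxylase-like, was the highest of them, at 1.61 ± 0.930 CPM in WT and 361 ± 15.2 in leptin overexpression. Log2 fold changes were 7.09 (SE 0.53), 6.27 (0.55), 4.94 (0.54) and 7.82 (0.63), with edgeR adjusted p of 0.00495, 0.00697, 0.0302 and 0.00495. ODC1, the ornithine decarboxylase that LOC100520618 resembles, was at 216 and 408 CPM in WT and 374 and 318 in leptin overexpression; reads may be divided between such similar genes, so the level of LOC100520618 is uncertain.

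At an unadjusted edgeR p under 0.05, 563 genes were higher and 741 lower. DESeq2 called 104 higher and 215 lower, including the 4 above, and limma-voom 1 and 0. Upper-quartile factors gave 7 and 4, and limma-trend on FPKM 89 and 261. More genes passed without a WT library than without a leptin overexpression library. Such a fit takes its spread only from the group that keeps 2 libraries, so its number of calls does not measure the weight of a library. Without leptin overexpression replicate 1 or 2, none of the 4 genes passed, STMN2 having adjusted p of 0.11 and 0.136. Their log2 fold changes were then 7.06 and 7.15 for STMN2, 6.46 and 6.10 for NEFL, 5.24 and 4.59 for LGI2 and 7.87 and 7.79 for LOC100520618, close to those with all libraries. Among GO terms, neuron projection was enriched among the higher genes through STMN2 and NEFL, 2 of the 2 annotated (Fisher's exact test, adjusted p = 0.0243); 0 KEGG pathways passed.

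**Figure D1:**
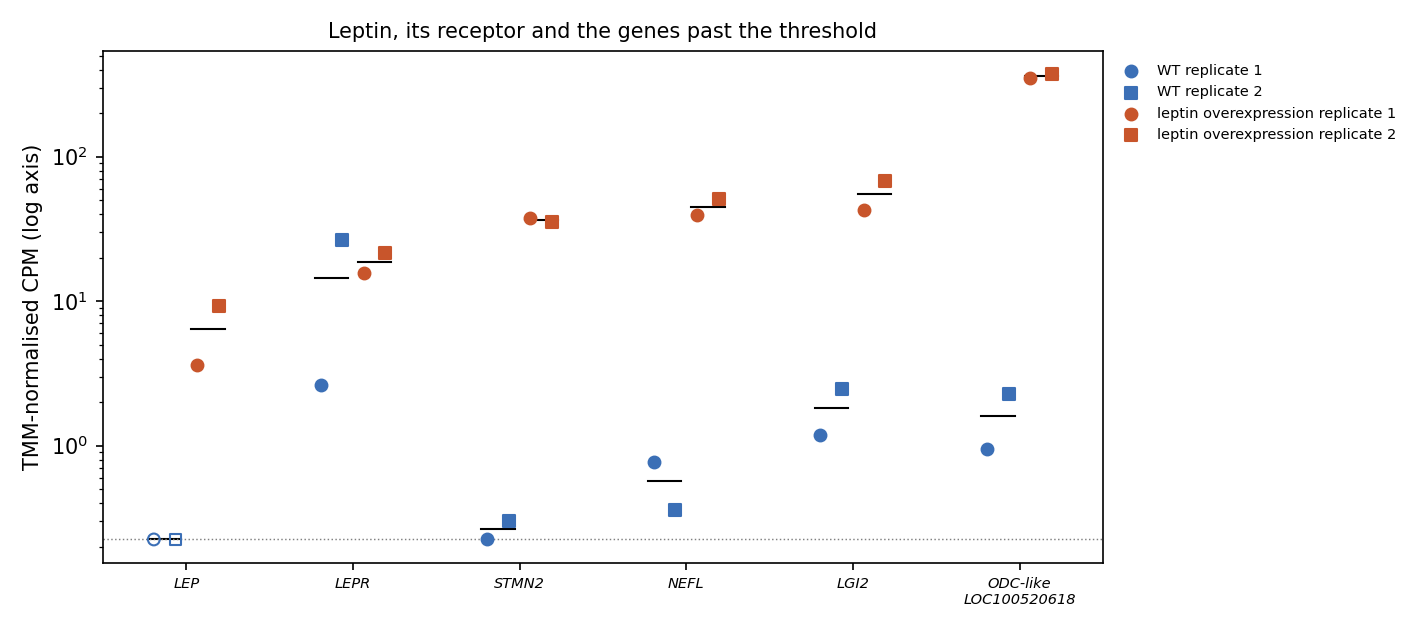
TMM-normalised CPM (log axis) of LEP, LEPR and the 4 genes past the edgeR threshold in each library; blue points are WT, orange points leptin overexpression, circles replicate 1, squares replicate 2, and bars group means. Open symbols, and the LEP mean, on the dotted line mark values under 0.224 CPM, the highest level of 3 counts among the libraries; LOC100520618 was at 350.1 and 371.6 CPM in leptin overexpression.

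The series design names steroidogenic enzymes and apoptotic markers. None of those analysed passed the threshold, and several differed more within WT than between genotypes. STAR, which moves cholesterol into mitochondria for steroid synthesis, was at 7022 and 15164 CPM in WT and 16546 and 23771 in leptin overexpression (log2 fold change 0.86, SE 0.66, edgeR adjusted p = 0.663). CYP11A1, the side-chain cleavage enzyme, was at 3822 and 12182 against 9244 and 7631 CPM, and HSD3B1, which forms progesterone, at 6222 and 8819.6 against 8503 and 8361. CYP17A1, needed for androgens, was at 157 and 1700.5 CPM in WT and 836 and 337 in leptin overexpression. CYP19A1, the aromatase that makes oestrogens, was at 9.21 and 197 CPM in WT and 197 and 161 in leptin overexpression. EdgeR adjusted p was 0.976, 0.93, 0.84 and 0.847 for these 4. The row described as BAX was at 207 and 184 against 217 and 169 CPM (adjusted p = 0.99). WT replicate 1 set several of these values. Without it the log2 fold changes of CYP11A1 and CYP19A1 were -0.55 and -0.16. Without WT replicate 2 those of CYP17A1 and CYP19A1 were 1.89 and 4.26. These fits hold none of the spread within WT, which for CYP19A1 was 9.21 against 197 CPM.

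The steroidogenesis list did not pass camera (difference 0.37, adjusted p = 0.127), nor did luteal cells (0.46, 0.349), granulosa cells (0.20, 0.844) or theca cells (0.059, 0.902). Without WT replicate 1 the first 2 differences were -0.16 and -0.24, and without WT replicate 2 they were 0.82 and 1.24, both past the threshold (adjusted p = 0.00476 and 0.00167). The granulosa list passed without leptin overexpression replicate 2 (0.71, adjusted p = 0.0461). The granulosa genes SERPINE2 and NR5A2 were at 300.2 and 594 against 647 and 663 CPM and at 656 and 402 against 495 and 559, respectively; DCN, of the theca list, was at 431 and 263 against 299 and 273. Pro-apoptotic genes gave a difference of 0.071 (adjusted p = 0.954) and anti-apoptotic genes 0.53 (0.0681). BNIP3L and AIFM1 were at 127 and 161 against 174 and 369 CPM and at 82.3 and 209.8 against 151 and 130.1, respectively; MCL1 and CFLAR, which oppose apoptosis, were at 307 and 408 against 429.6 and 615 and at 35.3 and 57 against 79.4 and 239, respectively. The leptin and JAK-STAT list gave 0.52 (camera adjusted p = 0.17), and 0.91 without WT replicate 2. LEP, the overexpressed gene, is itself on this list, so both differences partly restate the overexpression. The median log2 fold change of the list was 0.17. IL6ST and STAT3 were at 95.4 and 190.4 against 232 and 769 CPM and at 237 and 334 against 339 and 275, respectively.

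With all libraries, some genes of ovulation and prostaglandin synthesis passed the threshold only when edgeR p-values were adjusted over the list alone. That adjustment was added after the data were seen. The log2 fold change of PTX3 was 3.36 with all libraries, 2.61 without WT replicate 1 and 4.86 without WT replicate 2. PTGES, which makes prostaglandin E2, was at 221 ± 8.24 CPM (SD, n = 2) in WT and 1199.5 ± 218 in leptin overexpression (log2 fold change 2.44, SE 0.48; edgeR adjusted p = 0.209 over all genes and 0.0140 over the list alone). PTX3 and TNFAIP6, matrix proteins of the expanding cumulus, were at 28 and 134 against 639 and 1031 CPM and at 1.91 and 3.82 against 13.5 and 29.9, respectively. Over the ovulation and protease list alone, TNFAIP6 and PTX3 passed, with edgeR adjusted p of 0.0115 and 0.0123, against 0.209 and 0.225 over all genes. PTX3 is also on the luteal cell list, and passed over that list alone (edgeR adjusted p = 0.0348). The lists as wholes did not pass (prostaglandin 0.073, adjusted p = 0.986; ovulation and proteases 0.48, 0.46), though the latter did without WT replicate 2 (1.14, 0.0148). PTGFR, the prostaglandin F receptor through which luteal regression is triggered, was at 152 and 1316 CPM in WT and 445 and 352 in leptin overexpression.

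**Figure D2:**
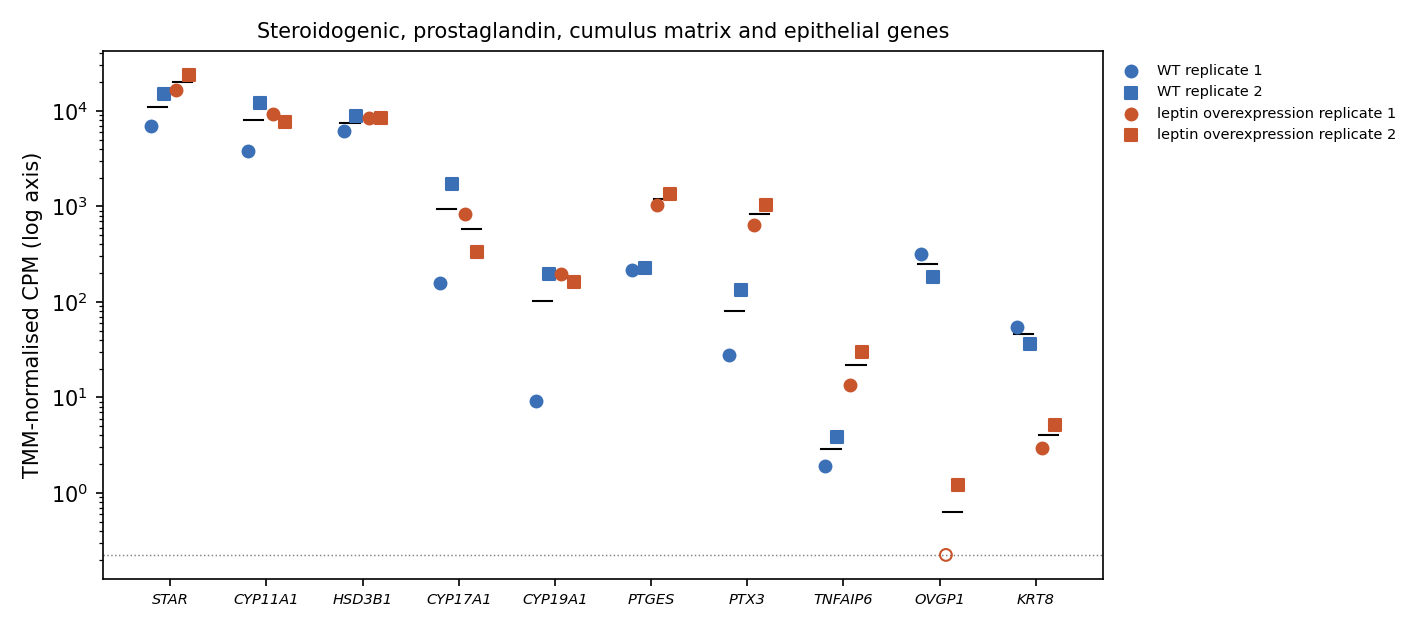
TMM-normalised CPM (log axis) of steroidogenic, prostaglandin, cumulus matrix and epithelial genes in each library; blue points are WT, orange points leptin overexpression, circles replicate 1, squares replicate 2, and bars group means. The open symbol on the dotted line marks a value under 0.224 CPM, the highest level of 3 counts among the libraries; CYP19A1 was at 9.21 CPM in WT replicate 1 and 197 in WT replicate 2.

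Of the 46 lists, 14 passed camera with the preset correlation of 0.01, 5 higher and 9 lower in leptin overexpression. With an estimated correlation 0 passed, and by fry 0. Estimated correlations of these 14 lists ran from -0.025 (smooth muscle and pericytes) to 0.93 (ribosomal proteins). They were 0.33 for oviduct and 0.45 for surface epithelium. The 2 residual degrees of freedom are few for such estimates, but the p-values with the preset correlation may be far too small. Epithelial genes were lower. All 12 tested oviduct epithelium genes had lower values (difference -3.09, adjusted p = 7.39e-08; adjusted p = 0.86 with an estimated correlation), 0 passing over all genes and 7 adjusted over the list alone. OVGP1, the oviductal glycoprotein, was at 316 and 183 CPM in WT and 0.0653 and 1.2 in leptin overexpression (edgeR adjusted p = 0.0919 over all genes, 5.54e-04 over the list alone; DESeq2 8.87e-06), and FOXJ1, the regulator of motile cilia, at 38.2 and 8.65 against 0 and 0.448. The cilium genes TEKT1 and SPAG6 were at 9.48 and 1.61 against 0.0653 and 0 CPM and at 14.2 and 1.97 against 0 and 0.149, respectively; TPPP3 was at 66 and 35.2 against 28.6 and 18.7. Of 10 surface epithelium and mesothelium genes, 9 were lower (-2.37, adjusted p = 3.14e-07; adjusted p = 0.86 with an estimated correlation), 0 passing over all genes and 6 over the list alone. KRT8 was at 45.6 ± 13.5 CPM in WT and 4.05 ± 1.57 in leptin overexpression (edgeR adjusted p = 0.0921 over all genes, 5.29e-04 over the list alone). CDH1 was at 63.2 and 31.1 against 0.457 and 3.51, WFDC2 at 9.07 and 11 against 0.392 and 0.672, and KRT18 at 6.44 and 2.74 against 0 and 0.374. EPCAM, an epithelial adhesion protein, was at 33.8 and 7.76 CPM in WT and 2.55 and 57.1 in leptin overexpression.

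**Figure D3:**
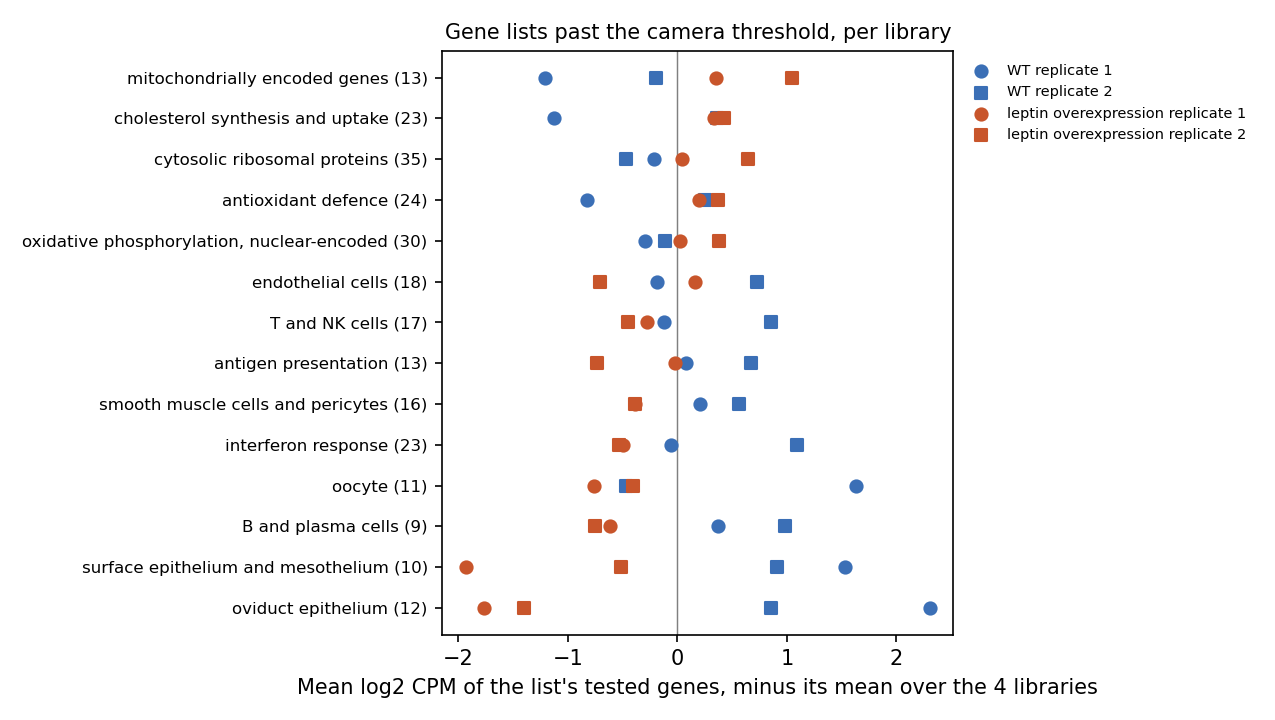
Mean log2 CPM of the tested genes of each list past the camera threshold (number of genes in parentheses), minus the list's mean over the 4 libraries; blue points are WT, orange points leptin overexpression, circles replicate 1 and squares replicate 2. For the oviduct list both WT libraries lay above 0, at 2.31 and 0.85, and for the oocyte list only WT replicate 1 did, at 1.63.

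The oocyte list was lower mainly against WT replicate 1. ZP3, of the egg coat, was at 31.7 and 4.42 CPM in WT and 3.98 and 2.69 in leptin overexpression, and the oocyte growth factors BMP15 and GDF9 were at 26 and 1.25 against 1.18 and 2.24 CPM and at 52.5 and 14 against 12.8 and 14.5, respectively. The list passed with all libraries (-1.09, adjusted p = 0.0407; adjusted p = 0.86 with an estimated correlation), with 10 of 11 tested genes lower and 0 past the threshold one by one, also adjusted over the list alone. Without WT replicate 1 the difference was 0.12 (adjusted p = 0.873), and without leptin overexpression replicate 1 it was -0.63 (0.594); without WT replicate 2 it was -2.01. UCHL1 and KIT, its most abundant members, were at 109 and 240.2 against 269 and 323 CPM and at 60.7 and 107 against 50.1 and 66.5, respectively.

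Immune, vascular and contractile lists were lower. Of 23 interferon response genes 22 were lower (-0.96, adjusted p = 6.39e-06), with MX2, an antiviral GTPase, at 32.4 and 80.6 CPM in WT and 14 and 10.8 in leptin overexpression and past the threshold over the list alone (0.0419). Of the B and plasma cell list 8 of 9 were lower (-1.28, 3.56e-04), 2 of them past it over the list alone: JCHAIN, of secreted antibodies, was at 19 and 39.3 against 4.24 and 6.72 CPM, and MZB1 at 1.54 and 7.52 against 0.522 and 0.523. T and NK cells had 13 of 17 lower (-0.66, 0.00781), antigen presentation 12 of 13 (-0.68, 0.00657), smooth muscle and pericytes 13 of 16 (-0.69, 0.00799) and endothelial cells 17 of 18 (-0.46, 0.0446). Each of these 6 had adjusted p = 0.86 with an estimated correlation. With the replicate number as a block the endothelial list no longer passed camera (adjusted p = 0.0641). MYH11 and DES, of smooth muscle, were at 421 and 231 against 69.9 and 107 CPM and at 41.6 and 107 against 17.8 and 23.8, respectively, and passed over the list alone (both 0.0388). CD247 and CD4, CD79A, B2M and CD74, STAT2, CALD1 and ACTA2, and PECAM1 and KDR, among the most abundant members of these lists, did not pass; CD247, CD79A, B2M and CALD1 had higher values in leptin overexpression, against the direction of their lists (log2 fold changes 0.26, 0.21, 0.23 and 0.54). Without WT replicate 2 the interferon list (-0.22, adjusted p = 0.199), T and NK cells (-0.26, 0.266), antigen presentation (-0.31, 0.33), smooth muscle (-0.45, 0.167) and endothelial cells (0.062, 0.969) no longer passed. Calls also ended for T and NK cells (0.0585) and smooth muscle (0.0806) without leptin overexpression replicate 1, and for antigen presentation (0.0879) and endothelial cells (0.037, 0.721) without leptin overexpression replicate 2. Without WT replicate 1 the interferon, T and NK cell and endothelial differences were -1.57, -1.12 and -0.91.

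Ribosomal and mitochondrial genes were higher. The ribosomal protein and mitochondrially encoded lists had been set beforehand as lists of sample quality. The share of mitochondrially encoded counts rose as the TMM factors fell, also between the 2 libraries of each group. It went from 6.89% at a factor of 1.34 in WT replicate 1 to 16.4% at 0.809 in leptin overexpression replicate 2. TMM factors come from the same counts, so this order is no separate evidence on the source of the shift. The ribosomal list went the other way within WT. Its mean log2 CPM, minus its mean over the libraries, was -0.21 in WT replicate 1 and -0.47 in WT replicate 2. Both factors were lower in leptin overexpression. The shift may follow the library as well as the genotype, and these cannot be told apart here. All 35 cytosolic ribosomal protein genes had higher values (0.76, adjusted p = 6.17e-08), as had all 13 mitochondrially encoded rows (1.48, 7.39e-08) and 29 of 30 nuclear genes of oxidative phosphorylation (0.49, 0.00147). RPS2 and RPS4X were at 3045 and 2863 against 3078 and 5316 CPM and at 1658 and 2029.9 against 2664 and 4394, respectively; COX1 and COX3 at 23403 and 73182 against 81424 and 73863 and at 8603 and 18479.5 against 27244 and 24563, respectively; ATP5F1A and SDHA at 664 and 837 against 763 and 833 and at 248 and 417 against 360.1 and 309, respectively. Cholesterol synthesis and uptake was higher in 19 of 23 genes (0.84, 8.42e-04), with HMGCS1 and MSMO1 at 491 and 2267 against 2885 and 3903 CPM and at 480.2 and 1527 against 2023 and 3665, respectively. Antioxidant defence was higher in 19 of 24 (0.64, 0.00951); GPX3 and GSTA1 were at 1536 and 10291 against 6961 and 3162 CPM and at 13.8 and 3218 against 2642 and 2559.7, respectively. Each of these 5 lists had adjusted p = 0.86 with an estimated correlation, and 0 of their members passed over all genes or over the list alone. Without WT replicate 1 the cholesterol (0.10) and antioxidant (0.12) lists no longer passed (adjusted p = 0.798 for both), and without leptin overexpression replicate 1 the cholesterol list had adjusted p = 0.0528. Without WT replicate 2 these 2 differences were 1.66 and 1.25. The mitochondrially encoded list was at 0.98 without WT replicate 1, and the ribosomal list at 0.53 without leptin overexpression replicate 2 (RPS2 0.075, against 0.51 with all libraries); both still passed.

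The other lists did not pass camera. Their differences, with the adjusted p, were -0.46 (0.106) for Wnt and Hedgehog signalling, 0.40 (0.107) for the unfolded protein response, -1.53 (0.112) for neutrophils, -0.41 (0.112) for complement and acute phase, 0.29 (0.112) for proliferation, 0.38 (0.112) for fatty acid oxidation, and -0.32 (0.164) for macrophages. Heat shock genes gave 0.34 (0.219), TGF-beta and BMP signalling -0.21 (0.33), fatty acid synthesis 0.31 (0.46), p53 targets 0.33 (0.46), angiogenesis and hypoxia -0.16 (0.46), mast cells 0.51 (0.46) and lymphatic endothelium 0.31 (0.46). Glycolysis gave -0.11 (0.643), autophagy and lysosome 0.13 (0.753), inflammatory cytokines -0.098 (0.753), the IGF axis -0.07 (0.753), insulin and AMPK signalling -0.019 (0.753), immediate-early genes 0.18 (0.788), hormone receptors 0.034 (0.844), adipocytes 0.12 (0.844) and collagen and stroma -0.03 (0.986). The median change had the opposite sign to the difference for theca cells (-0.22), hormone receptors (-0.24), adipocytes (-0.30), collagen (0.035), pro-apoptotic (-0.047), prostaglandin (-0.22), ovulation (-0.079), fatty acid oxidation (-0.033), p53 (-0.035) and autophagy (-0.015) lists; camera's direction was lower for theca cells, hormone receptors and adipocytes and higher for collagen. Members past the threshold over the list alone were HP, CFB and C3 of complement and acute phase, LTF and CSF3R of neutrophils, FABP4 of adipocytes and SLC16A3 of glycolysis, all lower, and UCP2, LPL and PPBP, higher. C3 was at 1036 and 505 CPM in WT and 229 and 111 in leptin overexpression, HP at 68.1 and 83.1 against 21.2 and 13.9, LPL at 25 and 80.3 against 225 and 189, and UCP2, a mitochondrial carrier, at 18.6 and 19.9 against 63.3 and 124; edgeR adjusted p over all genes was 0.266, 0.198, 0.308 and 0.198.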

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

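Camera on the annotation terms and the adjustment over the list alone were added after the results were seen, and the other alternatives were planned. Over all settings, single named genes kept their direction and side of the threshold in 860 comparisons, gained a call in 185, lost one in 11 and reversed in 54; gene lists did so in 327, 15, 41 and 30. The 4 genes called higher remained among the calls with RLE factors (4 higher, 0 lower), upper-quartile factors (7 and 4), no filter (84 and 168), the filter of 1 CPM (4 and 0), DESeq2 (104 and 215) and limma-trend on FPKM (89 and 261); limma-voom called 1 and 0. A fold threshold of 2 gave 4 and 0. Leaving out 1 library gave 0 to 258 higher and 0 to 423 lower, the lowest without leptin overexpression replicate 2 and the highest without WT replicate 2. Without the filter, edgeR's median prior degrees of freedom were 56, against 6.81 with it; the causes of these differences in calls were not tested. The median of all genes was -0.11 with upper-quartile factors and -0.31 on FPKM, against -0.012. Of 14 list shifts, 0 passed with an estimated correlation and 0 by fry, against 14 with RLE factors and 13 with the 1 CPM filter; leaving out 1 library gave 11 to 18. Enriched terms numbered 1 in the main test, 18 on DESeq2 calls, 1 with terms of 5 to 1000 genes and 45 by camera.

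With the replicate number as a block, 11 genes were higher and 12 lower, and 13 lists passed, the endothelial list being lost (adjusted p = 0.0641). Values that reversed under the block were CYP17A1 (0.039), NR5A2 (0.035), AIFM1 (0.095), EPCAM (-0.35) and GPX3 (0.24), none of them called. The labels do not say that a number marks a shared animal or day, and deviations of same-numbered samples from the group means correlated at -0.0995 across genes.

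With all libraries, the other reversed log2 fold changes or list differences, none of them called in either setting, were, with limma-trend on FPKM: CYP11A1 -0.12, HSD3B1 -0.23, STAT3 -0.29, EPCAM -0.59, CD247 -0.12, CD79A -0.12, B2M -0.076, ATP5F1A -0.42, SDHA -0.36 and ODC1 -0.21; with no filter: NR5A2 0.0085. They were also, with limma-voom: NR5A2 0.045, AIFM1 0.079, EPCAM -0.53 and GPX3 0.20, and with upper-quartile factors: ATP5F1A -0.012 and SDHA -0.074, and with the mean change tested by fry: theca cells -0.018, hormone and growth factor receptors -0.043, pro-apoptotic genes -0.0058 and prostaglandin and luteolysis genes -0.0036. Leaving out 1 library (W1 and W2 for the WT replicates, L1 and L2 for leptin overexpression) reversed these genes, given as lowest to highest: LEPR -0.54 (W1) to 2.78 (W2), CYP11A1 -0.55 (W1) to 1.12 (W2), HSD3B1 -0.086 (W1) to 0.41 (W2), CYP17A1 -1.55 (W1) to 1.89 (W2), CYP19A1 -0.16 (W1) to 4.26 (W2), DHDH -0.19 (L1) to 0.16 (L2), NR5A2 -0.34 (W2) to 0.37 (W1), DCN -0.62 (W2) to 0.10 (W1), STAT3 -0.14 (W1) to 0.35 (W2), AIFM1 -0.59 (W1) to 0.75 (W2), PTGFR -1.74 (W1) to 1.37 (W2), KDR -1.36 (L1) to 0.34 (W2), EPCAM -3.01 (L2) to 1.90 (W1), CD247 -0.26 (W1) to 1.01 (W2), CD4 -1.72 (W1) to 1.03 (W2), CD79A -0.045 (L2) to 0.46 (L1), B2M -0.39 (W1) to 1.25 (W2), ATP5F1A -0.091 (W1) to 0.24 (W2), SDHA -0.34 (W1) to 0.41 (W2), GPX3 -1.04 (W1) to 1.70 (W2), GSTA1 -0.33 (W1) to 7.53 (W2), ODC1 -0.26 (W1) to 0.66 (W2) and BMP15 -3.96 (W2) to 0.41 (W1). It reversed these lists, of which oocyte genes and endothelial cells were called with all libraries: steroidogenesis -0.16 (W1) to 0.82 (W2), luteal cells -0.24 (W1) to 1.24 (W2), granulosa cells -0.19 (L1) to 0.71 (L2), theca cells -0.14 (W1) to 0.33 (W2), oocyte -2.01 (W2) to 0.12 (W1), hormone and growth factor receptors -0.13 (W1) to 0.20 (W2), insulin, PI3K and AMPK signalling -0.062 (L1) to 0.041 (L2), IGF axis -0.23 (W1) to 0.18 (W2), pro-apoptotic genes -0.046 (L2) to 0.31 (L1), prostaglandin and luteolysis genes -0.24 (W1) to 0.46 (W2), collagen and stromal fibroblasts -0.15 (L1) to 0.22 (L2), endothelial cells -0.91 (W1) to 0.062 (W2), lymphatic endothelial cells -0.35 (W1) to 1.04 (W2), inflammatory cytokines and NF-kB targets -0.14 (W1) to 0.11 (L2), fatty acid and triglyceride synthesis -0.31 (W1) to 1.01 (W2), glycolysis -0.25 (W2) to 0.11 (W1), immediate-early genes -0.62 (W1) to 1.05 (W2), TGF-beta, BMP and activin signalling -0.37 (L1) to 0.066 (L2) and autophagy and lysosome -0.12 (W1) to 0.46 (W2). The causes of these reversals were not tested. The pseudocount alternatives were not run, since they applied only to a table without counts.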

Other observations

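The tests on mesothelium genes, on normalization and on the rise of neuron and Schwann cell genes, and camera on annotation terms, were chosen only after the results were seen; the direction of the cilium test was also anticipated from the oviduct list. DESeq2, which called 20 unchanged genes among 164 calls on simulated counts, called genes that edgeR did not. NEFM, the medium neurofilament chain, rose in leptin overexpression by DESeq2, from 0.681 and 4.18 CPM in WT to 21.5 and 41.8 (log2 fold change 3.72, SE 0.71, DESeq2 adjusted p = 4.15e-05; edgeR 0.231). RFLNA, a filamin-binding protein, was at 8.71 and 49.2 against 281 and 616 CPM (DESeq2 8.18e-07, edgeR 0.225), CHST4 at 0.227 and 1.01 against 9.92 and 8.96 (1.38e-04, 0.209), and SMARCA1, a chromatin remodeller, at 69.7 and 97 against 254 and 2237 (6.09e-06, 0.273). TNFSF18 was at 0.272 and 0.179 CPM in WT and 2.28 and 145 in leptin overexpression, nearly all of it in 1 library. Among abundant genes, CYB5A, an electron donor to CYP17A1, was at 1483 and 2904 CPM in WT and 5704 and 12519.9 in leptin overexpression (DESeq2 0.00482, edgeR 0.377), FMO1 at 102 and 883 against 2212 and 3346 (0.0178, 0.491) and the mitochondrial COX2 at 5548 and 9393 against 14347 and 33533 (0.0389, 0.518).

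Genes that fell by DESeq2 included the abundant FLNA, which crosslinks actin, at 801 and 434 CPM in WT and 233 and 187 in leptin overexpression (DESeq2 adjusted p = 0.0331, edgeR 0.365), and FBLN1, of the matrix, at 579 and 263 against 135 and 119 (0.0199, 0.317). OVGP1, C3 and MYH11 also fell (DESeq2 8.87e-06, 0.00225 and 0.00602). Of the genes with the largest falls, GPX2 was at 28.6 and 5.49 against 0 and 0.0747 CPM, TSPAN1 at 41.6 and 11.6 against 0 and 0.299, SPHKAP at 20.0 and 2.69 against 0 and 0.0747, and C20orf85 at 17.3 and 3.04 against 0 and 0. DMBT1, which has 2 rows in the table, and IGHV3-23, of a family whose members share reads, also fell by DESeq2. The DESeq2 calls were enriched in 18 terms, with cilium movement first (8 of 102 annotated lower genes, Fisher's exact test, adjusted p = 1.52e-07). Camera on the terms gave 45, with the KEGG ribosome pathway higher (median log2 fold change 0.62, adjusted p = 3.36e-10) and cilium movement lower (-2.80, 3.68e-06); 0 passed with an estimated correlation (adjusted p = 0.965 and 0.997 for these 2).

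The first pattern weighed was the lower level of oviduct and surface epithelium genes. The choice of scaling factors was argued against. With TMM, the median log2 fold change of the 22 tested genes was -2.94 (bootstrap 95% interval -4.41 to -1.01). This was the value closest to 0 among TMM, RLE, upper-quartile and no factors, and without factors it was -3.41. Factors move all genes of a library alike, so this test speaks only to the choice among these factors. The median of all genes went from -0.43 without factors to -0.012 with TMM. A second list of motile cilium genes, none of them in the first, had a median log2 fold change of -3.19 (27 of 27 tested lower), which is consistent with oviduct tissue carried along with the WT ovaries, WT replicate 1 above all. Without that library the median was -1.46 (24 of 26 lower), short of the -2 that this explanation was taken to need, and without WT replicate 2 it was -3.92. A change in the ovary's own ciliated cells was not tested. A second mesothelium list had a median of -0.13 (bootstrap 95% interval -1.65 to 0.28). This was too wide to decide whether the leptin overexpression samples held less ovarian surface epithelium. The median of that list was -0.40 without WT replicate 1 and -0.72 without WT replicate 2. Without leptin overexpression replicate 1 or 2 it was -0.43 or -1.08. SLC28A3 was taken out of that list because its value had been seen; with it the median was -0.59. An effect of genotype stays open and untested.

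The second pattern was the rise of STMN2 and NEFL. Neurons and nerve tissue in the leptin overexpression samples were argued against, since they would bring their other abundant transcripts. As a share of NEFL's rise in CPM, the median rise was 0 over 26 neuron genes (bootstrap 95% interval -0.0044 to 0.0033) and -0.0082 over 14 Schwann cell genes (-0.035 to -0.00051), under the bound of 0.1. Only NEFM, CHGA and UCHL1, and ERBB3 and NCAM1, were higher by that share or more. Against 606 and 678 counts of NEFL in leptin overexpression, TUBB3 had 0 and 0 (9 and 13 in WT), SNAP25 2 and 0 (3 and 5) and GAP43 12 and 12 (31 and 26). Another test was set before its own result was seen, but after STMN2 and NEFL had been called. In it, the median log2 fold changes of the tested genes of the 2 lists were 0.11 (-0.80 to 0.97) and -0.63 (-1.34 to 0.45). These intervals alone were too wide to decide. Both medians changed sign with 1 library left out. The neuron median ran from -0.11 (without leptin overexpression replicate 1) to 0.18 (without WT replicate 2). The Schwann cell median ran from -0.87 (without WT replicate 1) to 0.029 (without leptin overexpression replicate 2). A change in ovarian cells and an effect of genotype stay open and untested.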
